A study of Mus musculus with 24 samples.

How the data were processed

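RNA from whole mouse kidneys at embryonic day 18.5 was measured by bulk RNA sequencing in 24 libraries. Per the labels' protocols, tissue was kept in RNAlater, RNA was extracted with an RNeasy column kit, and libraries were made after poly(A) selection and read at 150 bp. The libraries come from 3 mouse lines, each with knockout embryos and the same number of control littermates: Dmrt2 (3 and 3), Hmx3 together with Hmx2 (6 and 6), and all 3 genes (3 and 3). The labels do not describe the alleles, nor which exons they remove. Groups and replicate numbers were taken from the sample titles. The labels do not say that each library of a group came from a separate embryo, so p-values measure the spread between these libraries, which can in part be technical.

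The values are counts of reads per gene, deposited by the authors without normalization in 4 tables of 54393 genes each, with 2 tables for the Hmx3 Hmx2 line (replicates 1 to 3 and 4 to 6). Per the submitters' processing notes, reads were trimmed with fastp 0.20.1, aligned with STAR 2.7.0e and counted with featureCounts 2.0.1, on the mouse build mm39, while the file headers name featureCounts 2.0.3. Per the file headers, exons were summed by gene name over a filtered GENCODE vM29 annotation in paired mode, without the option that counts read pairs, without a strand option and without the options that keep multi-mapping or overlapping reads. A count is therefore a read and not a fragment, and 87.9% to 94.1% of the counts between 1 and 19 were even numbers. Without strand, reads of a gene and of an antisense partner cannot be told apart, and reads that fit near-identical copies equally well were not counted for any of them, so values of such genes are uncertain. 15 genes had exons on several chromosomes, and no line lacked a gene name. 2 columns that match no sample were not used. The genome available was GENCODE vM21 on another build, so coordinates are those of the deposited tables, and this reference was used for gene types, names and transcript sequences only.

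Total counts per library ran from 52286824 to 127339273 reads. At these depths a count of 3 reads, taken as the floor for a gene with no reads, is worth 0.0236 to 0.0574 CPM (reads of a gene scaled to a common library total). The ratio of groups in which the knockouts held 1 to 3 reads in all is given with 95% limits from the exact Poisson interval of those reads, with the control reads taken as fixed. Reads were not marked with molecular identifiers and both reads of a pair are counted. Intervals and floors treat reads as independent, so they understate even the counting error and cover no other error. Mitochondrial genes took 0.98% to 2.54% of the counts. Libraries of the same group and table differed by more than sampling noise in all 24 pairs compared (chi-square per degree of freedom 5.61 to 29.71 over genes with a sum of at least 50 in the pair, on counts halved and rounded up because both reads of a pair are counted), so none was treated as a duplicate.

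Gene tests used edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with its default minimum count of 10 and total of 15, the robust quasi-likelihood F test, and Benjamini-Hochberg adjustment with a threshold of 0.05. A gene past that threshold is said to be called. Each knockout was compared with the controls of its own line, and the Hmx3 Hmx2 comparison had the deposited table as a term. Differences between knockout effects were tested in a single fit of the 24 libraries with the table as a term, so each effect is relative to controls of its own table and no comparison shares controls with another. Standard errors (SE) of log2 fold changes were computed as the absolute log2 fold change divided by the square root of F. CPM of the targeted genes use total counts, and CPM of other named genes use TMM-scaled totals. In differences between groups the knockout value comes first, so a positive log2 value is higher in the knockout.

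22 gene lists were fixed before the data were examined: type A, type B and non-A non-B, and pan-intercalated cells, principal cells, ureteric tip, ureteric epithelium, nephron progenitors, podocytes, proximal tubule, loop of Henle, distal convoluted tubule, stroma, endothelium, macrophages, erythroid cells, adrenal gland, skeletal muscle, adipose tissue, liver, proliferation, immediate early and heat shock genes, and the Notch pathway. 21 of them were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), again with an estimated correlation, and with fry. The adipose list was not tested, because 0 of its 5 members passed the filter in 2 of the comparisons and 1 in the triple comparison. Oxgr1, Car2, Kit, Slc4a1, Calb1, Wt1 and Rhbg are also expressed in other cells of kidney or blood, Slc4a1 and Car2 among them in erythroid cells.

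The genes named were set by a rule fixed before the data were examined. They are Dmrt2, Hmx2 and Hmx3, and per comparison the 8 largest increases and 8 largest decreases among called genes with a mean of at least 1 CPM whose knockout libraries all lay on one side of all controls (within each table for Hmx3 Hmx2), where clone-like symbols such as Gm or Rik are counted but not named. They are also the tested members of the 3 intercalated lists, up to 3 called members of each other list, the 6 genes with the smallest p per difference between effects, genes called in both the Dmrt2 and Hmx3 Hmx2 comparisons, and sex-linked genes where called. 1 gene that the rule selects is not reported here. Genes named outside it are said to be chosen after their values were seen.

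Alternatives fixed before the data were examined were the median-of-ratios size factors of DESeq2 within edgeR, no filter except 1 count, a minimum mean of 1 CPM, the DESeq2 1.42.0 Wald test, the replicate number as a block, leaving out each library in turn, a joint fit of all libraries, the mean log2 CPM (plus 0.5) of Ddx3y, Eif2s3y, Kdm5d and Uty as a covariate, and leaving out genes within 5 Mb of the targets and sex-linked genes. For Hmx3 Hmx2 they were also no table term and each table alone. Halved counts and leaving out chromosome 3 were chosen after seeing the data. Copies of coding genes were searched with BLAST 2.17.0. Tables were joined in Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.

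The steps were tested on simulated counts drawn from the means and library sizes of the real libraries, with 200 genes changed by known folds. In the Dmrt2 comparison 52.1% of genes changed 1.5-fold, 73.4% changed 2-fold and 89.7% changed 4-fold were recovered, and 8.2% of calls were false. For Hmx3 Hmx2 these shares were 67.6%, 86.4% and 98.4%, with 5.5% false, for the triple comparison 50.7%, 67.2% and 91.8%, with 8.5% false, and for the triple effect minus the Hmx3 Hmx2 effect 48.3%, 66.7% and 69.4%, with 6.2% false. A proximal tubule list lowered 1.5-fold was recovered by camera in all 3 comparisons, with 1, 0 and 0 of the other 20 lists called. Genes were drawn independently here, so this does not show how often lists of correlated genes are called falsely. When the real libraries were split otherwise, a median of 3, 2 and 4 lists were called.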

Results

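Whole kidneys of mouse embryos at embryonic day 18.5, shortly before birth, were profiled to ask how the transcription factors Dmrt2, Hmx2 and Hmx3 act on the subtypes of intercalated cells, the acid-base transporting cells of the collecting duct. Libraries of 3 Dmrt2 knockouts held 61563937 to 127339273 counted reads, against 71103531 to 77909704 in their 3 controls. Those of 6 Hmx3 Hmx2 knockouts held 52286824 to 66031622, against 55626702 to 91451356 in 6 controls. Those of 3 libraries labelled triple knockout held 94003922 to 113051369, against 108185205 to 110421376 in 3 controls. Y-linked genes were expressed in 1 of 3 Dmrt2 knockout libraries (replicate 1) and in all 3 of their controls, in 2 of 6 Hmx3 Hmx2 knockouts (1 and 4) and 4 of 6 controls (1, 3, 4 and 6), and in 2 of 3 libraries labelled triple knockout (1 and 3) and 2 of 3 controls (2 and 3).

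The targeted genes were examined first in every library. Dmrt2, a DM-domain transcription factor gene (chromosome 19, 25649775 to 25656355 on mm39), stood at 2.01 ± 0.378 CPM (SD, n = 3; 139 to 200 reads) in Dmrt2 knockouts and 13.7 ± 1.2 CPM in controls, 6.94-fold lower with an adjusted p of 1.4e-06. Hmx2 (chromosome 7, 131150502 to 131159743) and its neighbour Hmx3 (131144596 to 131146654) are homeobox genes. Hmx2 had 8 reads in total over the 6 Hmx3 Hmx2 knockouts and 807 over their controls, 84.9-fold lower in pooled CPM, and 2 against 872 reads in the triple comparison, 407.3-fold lower (95% limits 112.7 to 3362.9). Hmx3 was near the floor even in controls, with 6 against 34 reads in the Hmx3 Hmx2 comparison and 0 against 30 in the triple comparison. The latter is at least 9.34-fold lower with the floor of 3 reads taken over the group, if reads are taken as independent. Both reads of a pair are counted, so this bound is too high and the limits for Hmx2 are too narrow. In the libraries labelled triple knockout, however, Dmrt2 was not lower but higher than in controls, at 18.6 ± 0.984 against 11.4 ± 0.779 CPM (1683 to 2233 reads; log2 fold change 0.69 ± 0.08 SE, adjusted p = 0.0042), a call that ended without knockout replicate 3 (adjusted p = 0.0502). These counts do not show which exons were read, so they check the Hmx part of the label and go against its Dmrt2 part as a loss of transcript. Every direction drawn from these libraries below rests on their label.

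**Figure D1:**
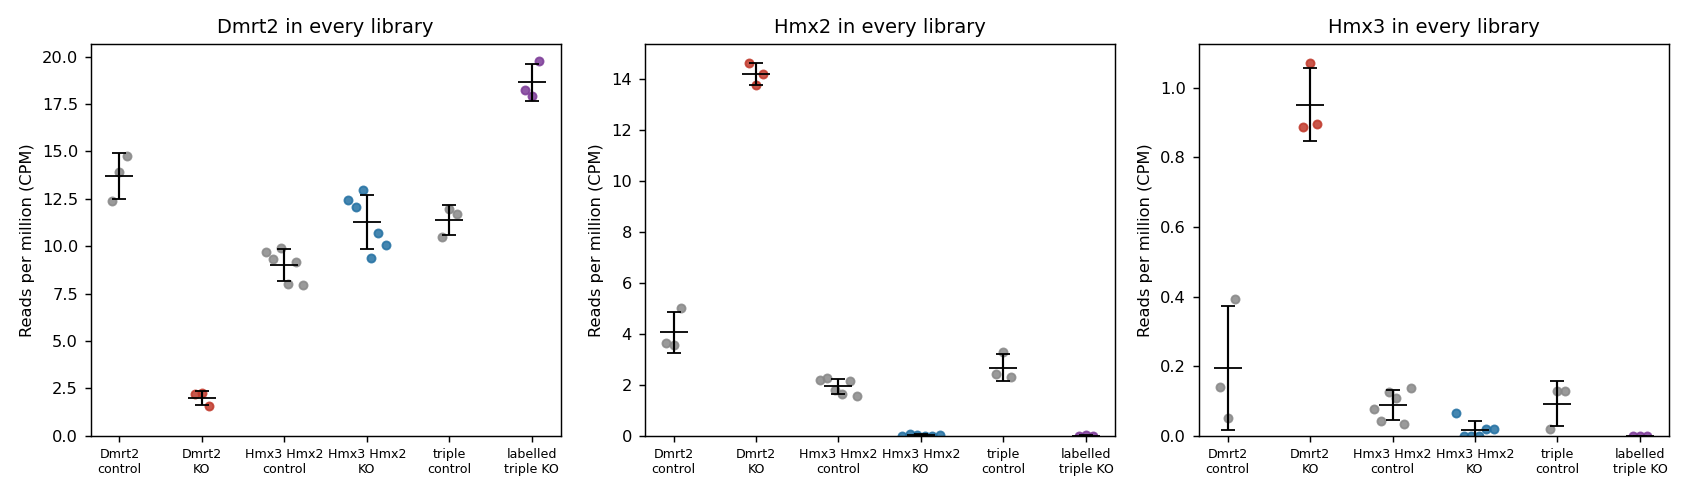
CPM of Dmrt2, Hmx2 and Hmx3 (linear axes from 0) in each library of the 6 groups. Points are libraries, lines the mean with SD. Dmrt2 lies at 1.57 to 2.26 CPM in Dmrt2 knockouts and at 17.9 to 19.8 CPM in libraries labelled triple knockout, and Hmx2 at 13.7 to 14.6 CPM in Dmrt2 knockouts against 3.56 to 4.99 CPM in their controls.

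The Dmrt2 comparison asks which genes depend on Dmrt2. Of 5 tested type A intercalated genes 3 fell in the knockout. Slc4a1, the basolateral chloride-bicarbonate exchanger of type A cells, went from 17.1 ± 1.57 to 3.73 ± 0.592 CPM (log2 fold change −2.19 ± 0.13 SE, adjusted p = 2.4e-06) and Aqp6, a channel of intracellular vesicles in these cells, from 14.6 ± 3.34 to 0.791 ± 0.159 CPM (−4.24 ± 0.21, adjusted p = 1.5e-06). Of 7 tested genes of type B and non-A non-B cells 3 rose and 1 fell. Among those that rose, Slc26a4, which encodes the apical anion exchanger pendrin, went from 4.56 ± 1.56 to 16.3 ± 1.26 CPM (1.84 ± 0.22, adjusted p = 0.016), and Slc4a9, a basolateral anion exchanger, from 48.1 ± 1.64 to 68.8 ± 6.53 CPM (0.52 ± 0.07, adjusted p = 0.0058). Hmx2 itself rose from 4.06 ± 0.812 to 14.2 ± 0.443 CPM (log2 fold change 1.80 ± 0.14, adjusted p = 3.0e-05). Hmx3, at 0.951 ± 0.105 against 0.195 ± 0.178 CPM, did not pass the test (2.28 ± 0.52, adjusted p = 0.098).

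By list, 3 of 5 type A members fell (Slc4a1, Aqp6 and the receptor tyrosine kinase gene Kit, −0.56) and 2 did not pass (Adgrf5 −0.27, Slc26a7 −0.26), with all 5 lower when adjusted over the list alone. The list was lower as a whole (camera adjusted p = 1.5e-43, and adjusted p = 0.0029 with an estimated correlation). Of 7 type B and non-A non-B members 3 rose (Slc26a4, Slc4a9 and the alkali-sensing receptor gene Insrr, 0.61), 1 fell (Oxgr1, a 2-oxoglutarate receptor, −0.81) and 3 did not pass (Sh2d4b 0.67, Slc4a8 0.03, Spink8 −0.40), with 4 higher and 2 lower when adjusted over the list alone. This list was called higher (camera adjusted p = 3.2e-05), but not with an estimated correlation (adjusted p = 0.138). Of 12 tested pan-intercalated members 1 fell, the proton pump subunit gene Atp6v1g3 (−0.75), and 5 when adjusted over the list alone. Foxi1, the transcription factor shared by intercalated cells, stood at 34.7 against 41.8 CPM (−0.27, adjusted p = 0.16), and Rhbg, Car2, Atp6v0d2, Atp6v1b1, Hepacam2, Atp6v0a4, Tfcp2l1, Rhcg, Bsnd and Atp6v1c2 lay between −0.87 and 0.01. The pan-intercalated list was called lower (adjusted p = 1.6e-06, and adjusted p = 0.138 with an estimated correlation).

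In all, 88 of 19807 genes were called, 37 higher and 51 lower, 17 of them with clone-like symbols. The other largest increases were Tldc2 (2.74 ± 0.14 SE, 9.58 against 1.44 CPM, adjusted p = 9.9e-07), Fgb, a fibrinogen chain gene (1.18), Mab21l3 (1.09), Zbtb37 (0.58) and Zdbf2 (0.56). The other largest decreases were Tpm3-rs7 (−5.58, 2.12 against 102 CPM), Hsd3b2, a steroid dehydrogenase gene (−3.77), Rps3a2 (−2.35), Rbm46 (−1.73) and Pck1, a key enzyme gene of gluconeogenesis (−1.60). Insrr, Mab21l3, Fgb, Hsd3b2 and Rbm46 lie on chromosome 3, which held 18 of the 88 calls where 4.5 would match its share of tested genes (one-sided Fisher exact p = 4.1e-07). This test takes genes as independent, which genes of 1 chromosome need not be. Tpm3-rs7 and Rps3a2 are copies of genes on that chromosome. In the Hmx3 Hmx2 knockouts and controls Tpm3-rs7 stood at 1.58 to 2.25 and 1.45 to 1.91 CPM. These values lay near the Dmrt2 knockouts (1.96 to 2.23) and far below the Dmrt2 controls (95.8 to 105). Hsd3b2 was likewise at 1.09 to 2.94 and 1.25 to 2.85 CPM there, against 23.5 to 29.7 in Dmrt2 controls. Rps3a2 and Rbm46 went the same way. For these genes the Dmrt2 controls thus stood apart, so their fall is not shown to be an effect of the knockout. Within 5 Mb of Dmrt2, 2610016A17Rik and Tmem252 were called, both chosen after their values were seen.

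The number of calls was 26 without knockout replicate 2, 195 without control replicate 1, 53 without control replicate 3, 54 without chromosome 3 genes, 429 with DESeq2, 676 without a filter and 13 with the Y-linked covariate. Slc4a1, Aqp6, Tldc2, Hmx2, Insrr, Slc4a9, Rps3a2 and Tpm3-rs7 were called in every alternative that tested them. The covariate ended the calls of Slc26a4 (log2 fold change 1.84, adjusted p = 0.34), Kit (0.23), Mab21l3 (0.093), Rbm46 (0.065), Atp6v1g3, Oxgr1, Fgb, Hsd3b2, Pck1, Zbtb37 and Zdbf2 (0.33 to 0.55). Slc26a4 was also not called without knockout replicate 1 (adjusted p = 0.055) or 2 (0.051) or control replicate 1 (0.064), Atp6v1g3 without knockout replicate 2 (0.098), and Oxgr1 without knockout replicate 1 (0.085), 2 (0.0507) or 3 (0.064) or control replicate 3 (0.059). Fgb was not called without knockout replicate 1 (0.078) or 2 (0.14), Hsd3b2 without knockout replicate 1 (0.12) or controls 1 (0.0514), 2 (0.068) or 3 (0.097), and Pck1 without chromosome 3 genes (0.0511), knockouts 1 (0.076) or 3 (0.085) or controls 1 (0.12), 2 (0.061) or 3 (0.14). Zbtb37 was not called in the joint fit (0.090) nor without knockouts 1 (0.070) or 2 (0.17) or controls 2 (0.062) or 3 (0.065), and Zdbf2 not in the joint fit (0.12) nor without knockouts 1 (0.13), 2 (0.19) or 3 (0.074) or controls 2 (0.067) or 3 (0.098).

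Lists of markers of other cells were also called in the Dmrt2 comparison. Other splits of the same libraries called up to 8 lists, against 9 here, intercalated lists included. With only 10 possible splits this cannot decide, so a change in other cells is neither shown nor excluded. Ureteric epithelium (median log2 fold change −0.17, adjusted p = 5.0e-04), stroma (−0.12, 0.011), liver (−0.33, 0.0034) and skeletal muscle (−0.63, 0.025) were called lower as lists, and distal convoluted tubule higher (0.29, 0.025). With an estimated correlation their adjusted p-values were 0.138, 0.138, 0.138, 0.178 and 0.337. The proximal tubule list was called lower (adjusted p = 0.011, and adjusted p = 0.605 with an estimated correlation) with a median of 0.003 and a mean of −0.08. No member of these 6 lists was called over all genes, while 4 of 8, 2 of 9, 1 of 5, 1 of 4, 1 of 5 and 4 of 11 were when adjusted over the list alone. The lists for principal cells, ureteric tip, nephron progenitors, podocytes, loop of Henle, endothelium, macrophages, erythroid cells, adrenal gland, proliferation, immediate early and heat shock genes and the Notch pathway were not called (adjusted p 0.054 to 0.90). When adjusted over the list alone, 1 principal cell, 1 nephron progenitor and 1 podocyte member were lower and 2 Notch members higher. For the immediate early list the median (−0.04) and mean (0.05) had opposite signs, and for the adrenal list both were −0.01 while the test pointed up.

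**Figure D2:**
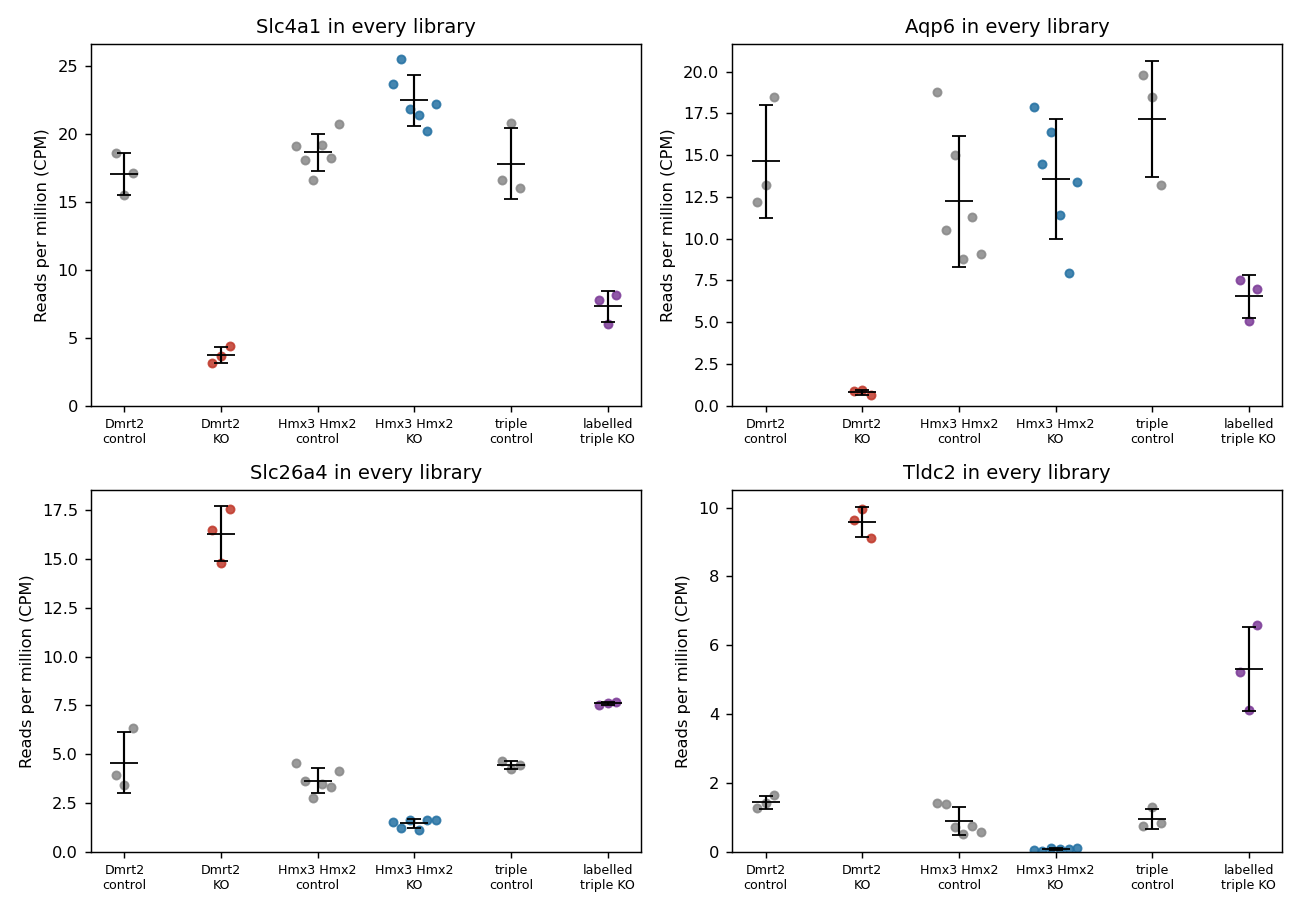
CPM of Slc4a1, Aqp6, Slc26a4 and Tldc2 (linear axes from 0) in each library of the 6 groups. Points are libraries, lines the mean with SD. Slc4a1 and Aqp6 are lower in Dmrt2 knockouts and in libraries labelled triple knockout than in their controls, while Slc26a4 and Tldc2 are higher in both and lower in Hmx3 Hmx2 knockouts.

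The Hmx3 Hmx2 comparison asks which genes depend on Hmx3 and Hmx2. Slc26a4 fell from 3.64 ± 0.622 to 1.47 ± 0.237 CPM (SD, n = 6; log2 fold change −1.31 ± 0.14 SE, adjusted p = 4.8e-04) and Tldc2 from 0.884 ± 0.398 to 0.0776 ± 0.0273 CPM (−3.47 ± 0.34, adjusted p = 1.4e-04). Tldc2 lay at 0.0302 to 0.106 CPM in the knockout libraries, near their floor of 3 reads (0.0454 to 0.0574 CPM). The size of this fold, and of differences between effects that use it, is therefore uncertain. Bub3, a mitotic checkpoint gene next to Hmx2 on chromosome 7 (131161951 to 131173624), rose from 105 ± 11.2 to 121 ± 12.1 CPM (0.21 ± 0.03, adjusted p = 0.0018). With Hmx2 these were the 4 genes called of 19050, while 940 had an unadjusted p under 0.05 and DESeq2 called 5. Dmrt2 stood at 11.3 ± 1.43 against 9.02 ± 0.850 CPM and did not pass the test (0.32 ± 0.06, adjusted p = 0.19), and lay higher in both deposited tables (0.38 and 0.27). Within replicates 1 to 3 and within 4 to 6, Slc26a4 changed by −1.31 and −1.30 (adjusted p 0.53 and 0.036), Tldc2 by −4.10 and −2.76 (0.069 and 0.071), Bub3 by 0.23 and 0.20 (0.82 and 0.40) and Hmx2 by −5.92 and −6.91 (0.0046 and 3.6e-05). Each table alone called 2 genes, as did a minimum mean of 1 CPM and the fit without genes near the targets and sex-linked genes, and Bub3 was not called without the table term (adjusted p = 0.9995).

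Type A and pan-intercalated genes were not called singly, but all 5 and all 12 tested members had log2 fold changes at or above 0 (medians 0.17 and 0.11). Examples are Slc4a1 (0.28 ± 0.06, 22.5 against 18.6 CPM, adjusted p = 0.76), Kit (0.17), Foxi1 (0.19), Atp6v0d2 (0.22), Tfcp2l1 (0.18) and Aqp6 (0.16). Both lists were called higher (adjusted p = 1.0e-05 and 7.4e-07), though both had an adjusted p of 0.145 with an estimated correlation, and 2 and 5 members were higher when adjusted over the list alone. Of 7 type B and non-A non-B members 1 fell (Slc26a4) and 6 did not pass, among them Oxgr1 (0.24, adjusted p = 0.76), Slc4a8 (0.17), Slc4a9 (0.02), Insrr (−0.07), Sh2d4b (−0.08) and Spink8 (0.07). Adjusted over the list alone 2 were higher and 1 lower, and the list was not called (adjusted p = 0.66, median 0.02 and mean −0.14).

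The lists for distal convoluted tubule (median 0.12, adjusted p = 9.7e-04) and principal cells (0.05, 0.034) were called higher, and those for immediate early and heat shock genes (−0.11, 0.0068) and endothelium (−0.05, 0.034) lower, with adjusted p-values of 0.145, 0.223, 0.223 and 0.223 with an estimated correlation. No member of these was called, and 1 distal convoluted tubule member was higher when adjusted over the list alone. The lists for ureteric tip and epithelium, nephron progenitors, podocytes, proximal tubule, loop of Henle, stroma, macrophages, erythroid cells, adrenal gland, skeletal muscle, liver, proliferation and the Notch pathway were not called (adjusted p 0.096 to 0.99), and 0 of their members were called when adjusted over the list alone. Median and mean differed in sign for nephron progenitors (−0.01 and 0.01), proliferation (−0.02 and 0.004) and skeletal muscle (0.01 and −0.01). The knockout effect differed between the 2 deposited tables for 0 of 19050 genes in edgeR, with 404 at an unadjusted p under 0.05 and 1 call by DESeq2.

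The triple comparison sets the libraries labelled triple knockout against their controls. Of 7 tested type B and non-A non-B genes 3 rose: Slc4a9 from 42.6 ± 4.92 to 86.7 ± 10.02 CPM (log2 fold change 1.03 ± 0.10 SE, adjusted p = 0.0065), Insrr from 18.1 ± 1.61 to 39.3 ± 3.84 CPM (1.12 ± 0.09, adjusted p = 2.5e-04) and Slc26a4 from 4.45 ± 0.227 to 7.62 ± 0.0921 CPM (0.77 ± 0.10, adjusted p = 0.0065). Slc4a1 fell from 17.8 ± 2.53 to 7.31 ± 1.15 CPM (−1.28 ± 0.13, adjusted p = 0.0041) and Aqp6 from 17.2 ± 3.53 to 6.55 ± 1.29 CPM (−1.39 ± 0.20, adjusted p = 0.033). Of type A members 2 of 5 fell and 3 did not pass (Slc26a7 −0.38, Kit 0.15, Adgrf5 0.05), with 3 lower and 1 higher when adjusted over the list alone. The list was called lower (adjusted p = 6.7e-05, and adjusted p = 0.21 with an estimated correlation). The other 4 type B and non-A non-B members did not pass (Sh2d4b 0.85, Slc4a8 0.20, Oxgr1 −0.27, Spink8 −0.74), and over the 7 members 5 were higher and 1 lower when adjusted over the list alone. This list was called higher (adjusted p = 1.5e-07, and adjusted p = 0.21 with an estimated correlation). Of 13 pan-intercalated members 1 fell, Atp6v1g3 (−0.48, adjusted p = 0.040), as when adjusted over the list alone, Foxi1 stood at 43.4 against 41.1 CPM (0.08, adjusted p = 0.48), and the list was not called (adjusted p = 0.19).

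In all, 222 of 21537 genes were called, 126 higher and 96 lower, 26 with clone-like symbols. Other large increases were Tgif2-ps2, a pseudogene (7.10, 3.98 against 0.0277 CPM), Tcea1-ps1 (2.55), Tldc2 (2.48 ± 0.24 SE, 5.32 against 0.954 CPM, adjusted p = 0.0018), Mab21l3 (1.58 ± 0.15, adjusted p = 0.0018) and Iqcn (1.21). The control mean of Tgif2-ps2 lies at the floor of 3 reads (0.0272 to 0.0277 CPM in these controls), so the size of its fold is uncertain. Genes matching pseudogenes were searched for the Dmrt2 comparison only. The rises of Tgif2-ps2 and Tcea1-ps1 are therefore not shown to be effects of the knockout. The largest decreases besides Hmx2 were AU015836 (−2.49), Slc22a26 (−2.29), Cd8a, a T cell coreceptor gene (−1.93), Slitrk1 (−1.79), Ifi202b (−1.53), Hp, which encodes haptoglobin (−1.50), and Acat3 (−1.47). Serpina1a of the liver list rose (0.70). Gldc, within 5 Mb of Dmrt2, was called, chosen after its values were seen.

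The number of calls was 20 without knockout replicate 3, 96 without knockout 2, 145 without control 1, 84 without control 2, 438 without control 3, 573 in the joint fit, 1085 with DESeq2 and 1510 without a filter. Insrr, Slc4a9, Tldc2, Mab21l3, Cd8a, Hmx2 and Tgif2-ps2 were called in every alternative that tested them. Aqp6 was not called with the Y-linked covariate (adjusted p = 0.051), without knockout 3 (0.14) or without control 1 (0.055) or 2 (0.11), and Slc26a4 (0.057), Tcea1-ps1 (0.054) and Slc22a26 (0.076) not without knockout 3. Atp6v1g3 was not called at a minimum of 1 CPM (0.052) nor without any 1 library but control 1 (0.050 to 0.11). Serpina1a and Ifi202b were not called in the joint fit (0.20 and 0.45), and Serpina1a and Acat3 not with the covariate (0.065 and 0.056). Leaving out 1 library ended the calls of Acat3, AU015836 and Iqcn in every case but control 3 (0.065 to 0.18), of Serpina1a in every case (0.062 to 0.13), of Slitrk1 without knockouts 1, 2 or 3 or control 2 (0.073 to 0.14), and of Hp and Ifi202b without knockouts 2 or 3 or control 2 (0.053 to 0.14).

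Lists of markers of other cells were called in the triple comparison too. Other splits of the same libraries called up to 10 lists, against 6 here, intercalated lists included. With only 10 possible splits this cannot decide, so a change in other cells is neither shown nor excluded. Macrophage (median −0.29, adjusted p = 0.032), proliferation (−0.17, 0.025) and principal cell (−0.13, 0.044) lists were called lower and the erythroid list higher (0.25, 0.0498), with adjusted p-values of 0.784, 0.784, 0.758 and 0.784 with an estimated correlation. No member of these was called over all genes, and 4 macrophage and 2 proliferation members were lower and 1 macrophage member higher when adjusted over the list alone. The list count was 3 without control replicate 1. Lists for ureteric tip and epithelium, nephron progenitors, podocytes, proximal tubule, loop of Henle, distal convoluted tubule, stroma, endothelium, adrenal gland, skeletal muscle, liver, immediate early and heat shock genes and the Notch pathway were not called (adjusted p 0.108 to 0.88). When adjusted over the list alone, 1 ureteric tip, 1 ureteric epithelium, 3 proximal tubule and 2 distal convoluted tubule members were lower, and 1 proximal tubule, 1 stroma, 1 liver and 4 Notch members higher. Median, mean and test differed in sign for the ureteric tip (0.07, −0.04, down), distal convoluted tubule (0.003, 0.15, down) and liver (0.11, −0.30, up).

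**Figure D3:**
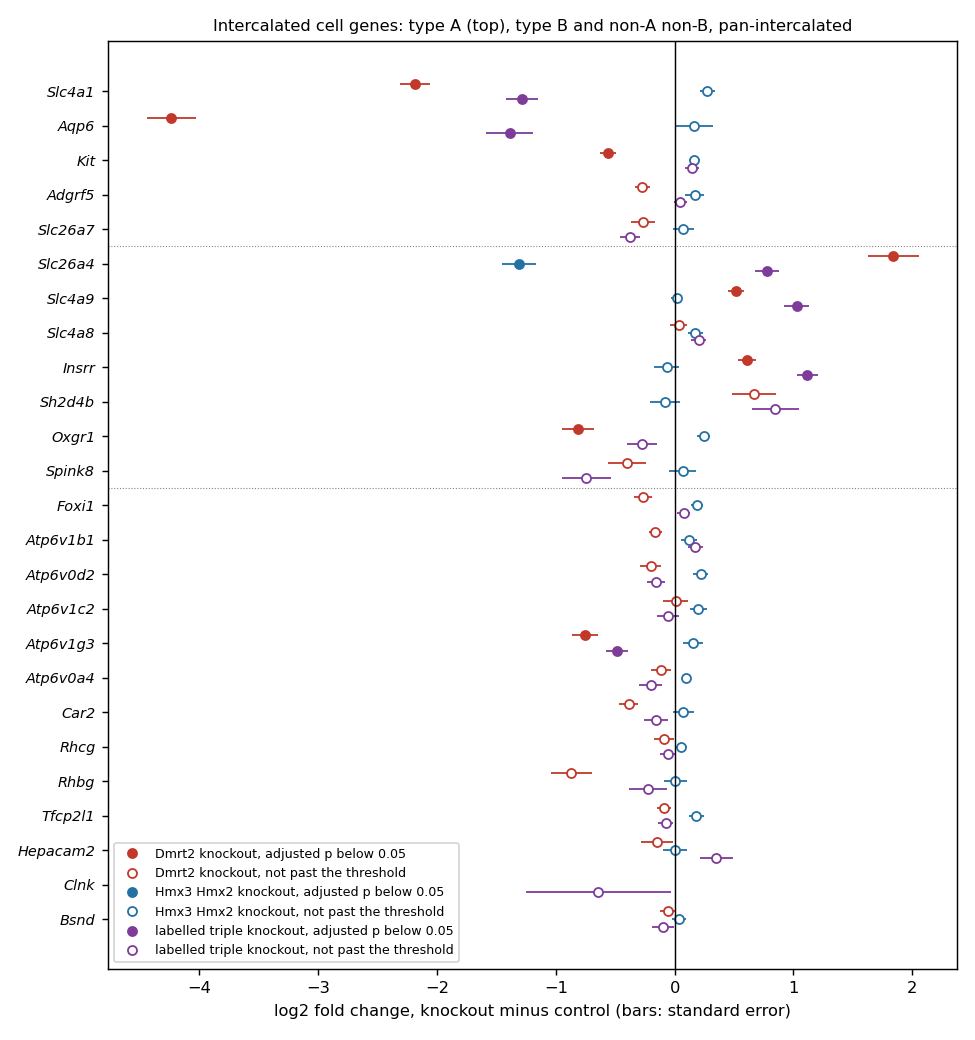
Log2 fold change (knockout minus control) with SE of each tested member of the 3 intercalated lists in the 3 comparisons. Filled points have an adjusted p below 0.05. Slc4a1 and Aqp6 lie below 0 in the Dmrt2 and triple comparisons, and Slc26a4 lies at 1.84, −1.31 and 0.77 in the Dmrt2, Hmx3 Hmx2 and triple comparisons.

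The knockout effects were then tested against each other. The Dmrt2 and Hmx3 Hmx2 effects differed for 34 of 22101 genes, 6 higher and 28 lower in the Dmrt2 effect, among them Slc4a1 (−2.46 ± 0.15 SE), Aqp6 (−4.41 ± 0.32), Slc26a4 (3.15 ± 0.23), Tldc2 (6.24 ± 0.38), Kit (−0.73), Oxgr1 (−1.06), Foxi1 (−0.46 ± 0.09, adjusted p = 0.019) and Rhbg (−0.88, adjusted p = 0.036). The count was 94 with DESeq2, 13 without Dmrt2 knockout replicate 2 and 20 without Dmrt2 control 3. The triple and Dmrt2 effects differed for 87 genes (53 higher and 34 lower in the triple effect). Here the fall of Slc4a1 and Aqp6 was smaller in the triple effect by 0.90 ± 0.17 (adjusted p = 0.011) and 2.85 ± 0.36 (5.1e-04), and Kit lay higher by 0.70 ± 0.09 (2.6e-04), while Slc26a4 (−1.07, adjusted p = 0.059) and Slc4a9 (0.51, 0.058) did not pass. That count was 254 with DESeq2, 37 without triple knockout replicate 3, and 44 and 46 without Dmrt2 knockouts 2 and 3.

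The triple and Hmx3 Hmx2 effects differed for 214 genes (138 higher and 76 lower in the triple effect). Of 25 tested intercalated members 7 were among them: Slc26a4 (2.08 ± 0.23), Slc4a9 (1.00 ± 0.10), Insrr (1.18 ± 0.16) and Sh2d4b (0.92) higher, and Slc4a1 (−1.56 ± 0.15), Aqp6 (−1.56 ± 0.28) and Atp6v1g3 (−0.64) lower. Tldc2 (5.98 ± 0.39) was higher, and the potassium channel subunit gene Kcne1 (−1.12) and the phosphatase gene Dusp14 (−0.50) were lower. This count was 551 with DESeq2, 49 without triple knockout 3, 131 without triple knockout 2 and 129 without triple control 2. The triple effect departed from the sum of the other effects for 88 genes (59 higher, 29 lower), among them Aqp6 (2.69 ± 0.39, adjusted p = 0.0033), Kit (0.53, 0.018), Tldc2 (3.24 ± 0.46, 0.0015) and the poly(A)-binding protein gene Pabpn1 (0.69 ± 0.10, 0.0016), but not Slc4a1 (0.62, adjusted p = 0.19) or Slc26a4 (0.24, 0.81). That count was 243 with DESeq2, 32 with the Y-linked covariate, 33 without triple knockout 3, 34 and 40 without Dmrt2 knockouts 2 and 3, 138 without Dmrt2 control 3, 58 without Hmx3 Hmx2 control 1 and 40 without triple control 3.

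Calls shared between comparisons were few. The Dmrt2 and Hmx3 Hmx2 comparisons had 3 called genes in common, Hmx2, Slc26a4 and Tldc2, all higher in the first and lower in the second, where 0.01 would be shared in opposite directions by independent lists. Hmx2 is targeted in the second, so its fall there was fixed by the design, and only Slc26a4 and Tldc2 inform on the overlap. The Dmrt2 and triple comparisons had 17 in common of 82 and 219 calls among 19520 genes tested in both. 9 were higher in both (0.24 by independent lists), among them Slc26a4, Slc4a9, Insrr, Tldc2 and Mab21l3. Another 6 were lower in both (0.22), among them Slc4a1, Aqp6, Atp6v1g3 and Acat3. The 2 opposite (0.47) were the targeted genes Dmrt2 and Hmx2. Over all 82 Dmrt2 calls 57 (69.5%) had the same sign in the triple comparison, against 57.7% of all genes tested in both, and the log2 fold changes had a Pearson r of −0.35 across these calls and 0.047 across all genes, which are not independent replicates. The calls behind the r of −0.35 include the targeted Hmx2 (1.80 and −8.45) and the chromosome 3 copy Tpm3-rs7, both with large opposite changes. This r was not computed without them, so it does not show that the other calls moved oppositely. The number in common was 104 with DESeq2 (87 the same way) and 36 in the joint fit (24 the same way). The Hmx3 Hmx2 and triple comparisons shared Hmx2, targeted and lower in both, and Slc26a4 and Tldc2, lower in the first and higher in the second.

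**Figure D4:**
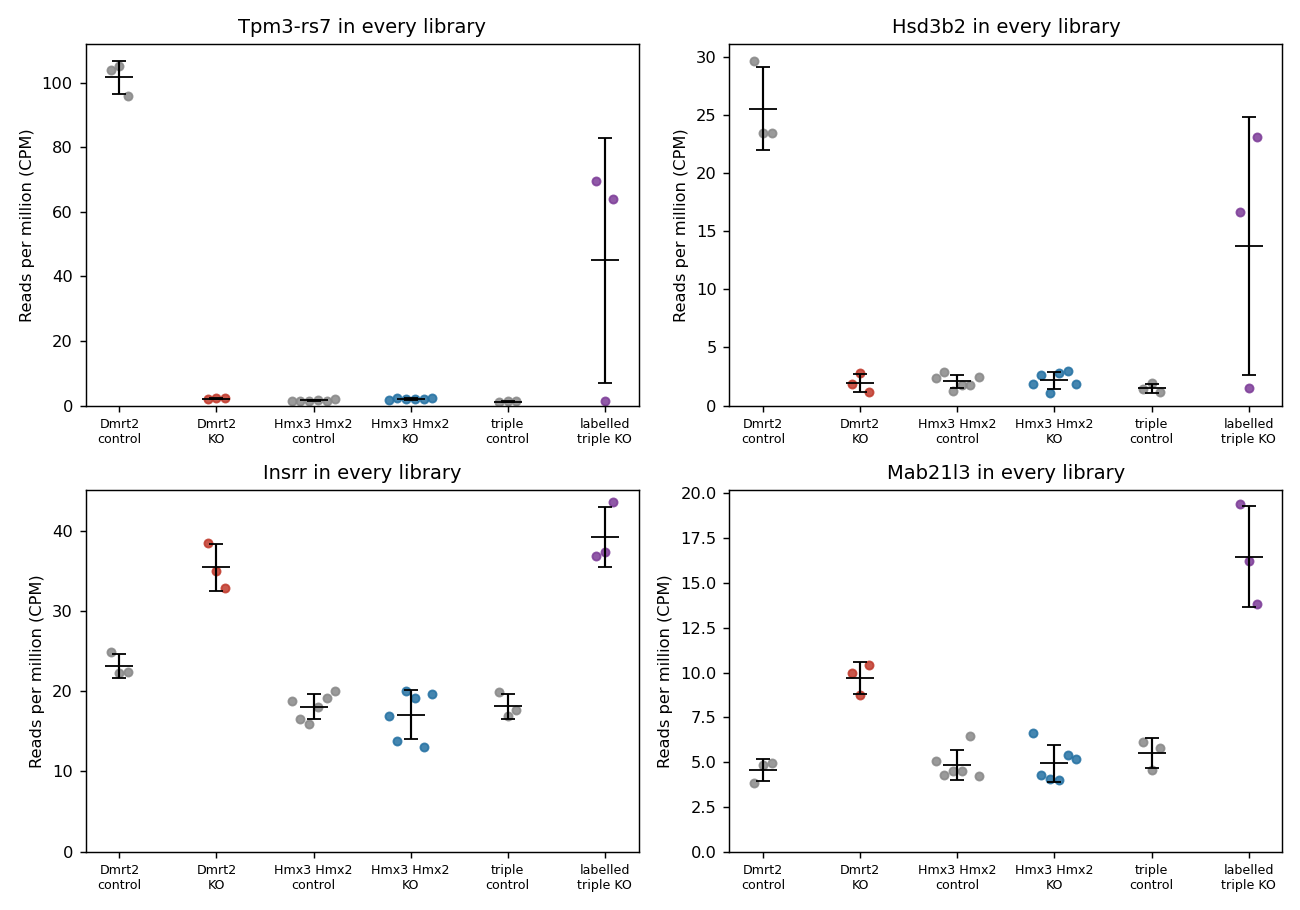
CPM of Tpm3-rs7, a copy of Tpm3, and of Hsd3b2, Insrr and Mab21l3 on chromosome 3 (linear axes from 0) in each library. Points are libraries, lines the mean with SD. Tpm3-rs7 lies at 95.8 to 105 CPM in Dmrt2 controls, at 1.96 to 2.23 CPM in Dmrt2 knockouts and at 69.6, 1.40 and 63.8 CPM in libraries 1, 2 and 3 labelled triple knockout.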

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

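The tests of the Dmrt2 transcript in the libraries labelled triple knockout, and that of Insrr and Mab21l3 against the chromosome 3 segment, were chosen after the result was seen, whereas the splits of the libraries, the test of the gene copies and the test of sex were written before.

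The Dmrt2 and Hmx3 Hmx2 effects differed for 34 genes, led by Dmrt2 (−3.13), Hmx2 (8.09), Tldc2 (6.24), Slc4a1 (−2.46), Slc26a4 (3.15) and Aqp6 (−4.41) on the log2 scale. The triple and Dmrt2 effects differed for 87, led by Dmrt2 (3.48), Hmx2 (−10.18), Tpm3-rs7 (10.77), Gm9347 (8.64), Kit (0.70) and Rps3a2 (4.12). The triple and Hmx3 Hmx2 effects differed for 214, led by Tldc2 (5.98), Slc4a1 (−1.56), Slc4a9 (1.00), Slc26a4 (2.08), Kcne1 (−1.12) and Dusp14 (−0.50). The triple effect departed from the sum of the other effects for 88, led by Dmrt2 (3.16), Tpm3-rs7 (10.46), Tldc2 (3.24), Pabpn1 (0.69), Gm9347 (8.62) and Rps3a2 (4.16). Each of these passed the edgeR test of the difference itself (adjusted p at most 0.0016), and the folds of Hmx2 and of other genes near 0 reads depend on the prior count. Tpm3-rs7, Gm9347 and Rps3a2 are copies of genes on chromosome 3, and their differences are not shown to be effects of the knockouts. In libraries 1, 2 and 3 labelled triple knockout Tpm3-rs7 stood at 69.6, 1.40 and 63.8 CPM and Rps3a2 at 7.88, 1.73 and 7.84 CPM. Library 2 thus lacked the rise of both genes.

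In groups of 6 libraries, single libraries stood apart in 3 of 58 tests, where 2.9 would by chance at 1 in 20. The gap to the nearest library was 0.806 of the range for Hepacam2 in Hmx3 Hmx2 control 3 (5.14 CPM, nearest 4.45), 0.719 for Slc26a7 in Hmx3 Hmx2 knockout 1 (15.3, nearest 11.2) and 0.631 for Slc4a9 in Hmx3 Hmx2 control 3 (40.8, nearest 47.0).

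Other splits of the same libraries were fitted for each count. For the Dmrt2 and triple comparisons the 10 possible splits are too few for a share under 0.05: the real splits gave 88 and 222 genes against a highest other of 21 and 9, with 1 of 10 splits as large in each, and 9 and 6 lists against 8 and 10, with 1 and 2 of 10. Of 100 splits drawn for Hmx3 Hmx2, 3 gave as many as 4 genes (highest other 14), the real split included, a share under 0.05. The 4 genes include the targeted Hmx2, so this share does not exclude chance for the others. For the lists 9 splits gave as many as 6 (highest other 9), so chance cannot be excluded. For the difference between the 2 Hmx3 Hmx2 tables, all 100 splits gave as many as the 0 observed, as any split must, so this cannot decide. The highest gave 559, which may point to a structure of these libraries, not examined further. For the differences between effects, 1 of 100 splits reached 34 (Dmrt2 minus Hmx3 Hmx2, highest other 18) and 3 reached 87 (triple minus Dmrt2, 322). Likewise 1 reached 214 (triple minus Hmx3 Hmx2, 156) and 3 reached 88 (triple minus the sum, 254). Each share is under 0.05. These splits regrouped the libraries of all lines at once, so they ask whether there is any knockout effect, not whether effects differ. They therefore cannot exclude chance for a difference. The splits with 322 and 254 genes may also point to a structure of the libraries, not examined further.

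The Dmrt2 transcript was not lower in the libraries labelled triple knockout. That they carry the Hmx3 Hmx2 knockout alone is argued against by 7 of 25 intercalated members that differed between the triple and Hmx3 Hmx2 effects, among them Slc4a1, Aqp6 and Slc26a4. The same Dmrt2 allele as in the Dmrt2 line is argued against by the difference of 3.482 ± 0.150 (SE) between the Dmrt2 effects, far above the Hmx3 Hmx2 effect on Dmrt2 (0.32 ± 0.06). A Dmrt2 allele whose transcript remains may account for the pattern, since 6 of the 8 intercalated members called in the Dmrt2 comparison moved the same way here, but counts per gene do not show exons, which keeps this open.

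Many calls of the Dmrt2 comparison lay on chromosome 3 (18 of 88, from 55.5 to 135 Mb) or were copies of genes there. Of 14 called pseudogenes with a matching coding gene (at least 90% identity over 50% of the copy), 100% matched a gene on chromosome 3, against 3.7% of 868 others (one-sided Fisher exact p = 1.3e-19). The test takes copies as independent, but several match the same gene (Phgdh, Cnn3 or Rps3a1), so this p overstates the evidence. A strain segment on chromosome 3 that differs between the Dmrt2 knockout and control libraries may account for this, with reads of variant alleles aligned to copies. In libraries 1, 2 and 3 labelled triple knockout Tpm3-rs7 stood at 69.6, 1.40 and 63.8 CPM, against 1.06 to 1.36 in their controls (log2 fold change 5.20 ± 1.62 SE, adjusted p = 0.23, not called), and of the 18 chromosome 3 calls 10 had the opposite sign there and 8 the same. Of markers of the segment (Tpm3-rs7, Hsd3b2, Rps3a2 and Rbm46), 4 of 4 went from lower in the Dmrt2 comparison to higher here by over 2 SE, though uncalled here. They were chosen after their values were seen, so this tally is no test. In library 2 they lay at or near their controls (Hsd3b2 1.49 CPM against 1.17 to 1.92, Rps3a2 1.73 against 1.57 to 1.80, Rbm46 1.40 against 0.917 to 1.42). Yet in libraries 1, 2 and 3 Insrr stood at 36.8, 37.3 and 43.5 CPM (controls 16.9 to 19.9) and Mab21l3 at 19.4, 16.2 and 13.8 CPM (controls 4.57 to 6.13). Both were higher by at least 1.117 on the log2 scale. Their rise in library 2 argues against this segment as its cause in the triple comparison, though this rests on 1 library. In the Dmrt2 comparison the part of the segment in their rise stays open.

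Sex was unequal between Dmrt2 knockouts (1 of 3 with Y-linked genes) and controls (3 of 3). Sex as the cause of the calls is argued against only as far as sex coefficients from the 18 libraries of other lines carry over. They predicted a median of 0.017 of the observed log2 changes over 84 calls, and 0 of these calls had a share of 0.5 or more. The 95% bootstrap interval of the median (−0.0066 to 0.031) resampled genes, which are not independent. It leaves out the error of the coefficients and is too narrow. For the 5 sex-linked genes Ddx3y, Eif2s3y, Kdm5d, Uty and Xist the same coefficients predicted a median share of 4.8, so the share was not calibrated there. The prediction uses a difference of mean log2 scores (−4.03). The observed change instead compares counts of groups, of which the knockouts mix both sexes (Ddx3y 21.0 against 54.5 CPM). With the Y-linked covariate the calls went from 88 to 13, while the median absolute log2 change went from 0.72 to 0.669, the median SE from 0.11 to 0.164 and the residual degrees of freedom from 4 to 3, and 88 of 88 kept their sign. The calls thus ended at nearly the same folds with larger SEs. In each of the 88 calls all 3 knockouts lay on one side of all 3 controls. This includes knockout replicate 1, which had Y-linked genes as the controls did, but that comparison rests on 1 library. Effects of sex that differ between the lines stay open.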

How the results depend on the processing

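Halved counts and leaving out chromosome 3 genes were chosen after seeing the data, while all other alternatives were fixed before. Another scaling moved no count by over 1.5 times, and no result turned direction with a call. Over 2617 alternatives of named genes 2478 kept their side of the threshold, 113 ended a call and 26 gave one, with 36 changes of sign among uncalled genes. Over 819 alternatives of lists the numbers were 724, 74 and 21. Calls of the Dmrt2 comparison (88) were 676 without a filter, 429 with DESeq2, 13 with the Y-linked covariate, 54 without chromosome 3 genes (fewer genes tested) and 26 (without knockout 2) to 195 (without control 1) leaving out 1 library. Calls of Hmx3 Hmx2 (4) were 2 at a minimum of 1 CPM, 2 without genes near the targets and sex-linked genes, and 2 in each table alone (fewer genes or samples), and 4, the same 4 genes, leaving out any library. Calls of the triple comparison (222) were 1510 without a filter, 1085 with DESeq2, 573 in the joint fit, and 20 (without knockout 3) to 438 (without control 3). Dmrt2 minus Hmx3 Hmx2 (34) was 94 with DESeq2 and 13 to 49. Triple minus Dmrt2 (87) was 254 and 37 to 118. Triple minus Hmx3 Hmx2 (214) was 551 and 49 to 279. Triple minus the sum (88) was 243, 32 with the covariate, and 33 to 138. Differences between the Hmx3 Hmx2 tables (0) were 3 without a filter, 1 with DESeq2 and 0 to 1. With an estimated correlation 1, 0 and 0 lists were called (from 9, 6 and 6), with fry 5, 0 and 2, and leaving out 1 library 6 to 11, 4 to 7 and 3 to 8. Calls shared by the Dmrt2 and triple comparisons (17) were 104 with DESeq2 and 36 in the joint fit. Except where fewer genes or samples show it, and for the covariate in the Dmrt2 comparison, where the SEs grew, the cause was not tested. The replicate number as a block moved the triple count from 222 to 51 (41 shared; Slc4a1, at adjusted p = 0.0509, and Aqp6, at 0.068, were not among them), the Dmrt2 count to 80 and the Hmx3 Hmx2 count to 5, but the numbers do not pair the libraries (same-number correlations 0.04 to 0.08, −0.01 to 0.22 and −0.17 to 0). In the Hmx3 Hmx2 and triple lines not every library correlated best with its own number, and in the Dmrt2 line number 3 was level with another (0.04). Depth limits what can be said of Hmx3, with 30 to 42 reads per control group.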

Other observations

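The tests here are the gene tests of the report, and all genes in this part were chosen after their values were seen. In the triple comparison Cyp24a1, which breaks down active vitamin D, fell from 59.6 ± 6.60 to 28.5 ± 1.51 CPM (log2 fold change −1.07 ± 0.08 SE, adjusted p = 2.6e-04), S100g, a calcium-binding protein gene, from 171 ± 32.9 to 61.8 ± 0.394 CPM (−1.47 ± 0.15, adjusted p = 0.024) and Kl, which encodes Klotho, from 381 ± 59.6 to 252 ± 6.49 CPM (−0.59 ± 0.10, adjusted p = 0.045). Calb1, another calcium-binding protein gene, stood at 71.5 against 158 CPM (−1.14 ± 0.18, adjusted p = 0.080). In the Dmrt2 comparison none of the 4 was called (Cyp24a1 −0.15, S100g −1.04, Kl −0.15, Calb1 −0.38). The triple effect minus the Dmrt2 effect did not pass the test for any of them, at −0.93 for Cyp24a1 (adjusted p = 0.45), −0.43 for S100g (0.61), −0.44 for Kl (0.37) and −0.76 for Calb1 (0.25).

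Itgb6, an integrin subunit gene, rose in both the Dmrt2 (0.49 ± 0.07 SE, adjusted p = 0.0097) and triple (0.52 ± 0.05, adjusted p = 0.0018) comparisons, as did P3h2, a collagen prolyl hydroxylase gene (0.43 and 0.42).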
